A study of Mus musculus with 4 samples.

How the data were processed

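The series holds 4 Visium libraries of mouse brain hemispheres, 2 sham and 2 with GL261 cells, and the group of each section was taken from its treatment label. The deposited values are UMI counts per gene and spot, with spot positions, and no normalization was applied to them per the file headers and values, which are whole numbers. Reads were processed by the authors with Space Ranger against mm10, per the submitters' processing notes; the version and the annotation release are not given in the sources used here. The matrices hold the spots that the deposited position tables mark as lying under tissue, and all of these were used. Total counts per section ranged from 10036123 to 29600917 UMIs. Near-identical genes (MHC class I genes, Ly6c1 and Ly6c2, the alpha globin genes and ribosomal protein genes with pseudogenes) can share reads, and the counting's treatment of such reads is not given in the sources used here. Clec7a, a member of the activated microglia list, was not analysed here. No doublet caller was run, since a spot can hold several cells, and no cell-type makeup was estimated.

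The groups, designs, gene lists, zone rule, rule for named genes and nearly all alternatives were fixed before the data were examined; the exceptions are named as chosen after seeing the data. A spot's proliferation level was the count of 29 cell cycle genes per 10000 counts, both summed over the spot and its up to 6 touching tissue spots. The threshold was the higher of the sham sections' 99th percentiles, and the zone was formed by tumour-section spots above it in connected groups of at least 20 spots. The border was 1 to 3 hexagonal steps outside the zone, distant tissue 6 or more steps, and steps 4 and 5 were left out. Proliferation genes are not a finding between zones, since the rule uses them. Sham spots with few counts raise the threshold: taken from sham spots of at least 1000 UMIs, an alternative chosen after seeing the data, it was 2.997 in place of 11.4 per 10000, while the 95th percentile and a higher one, exceeded by 1 in 1000 sham spots, gave 1.45 and 27.95. Regions were Leiden clusters of all spots at resolution 0.5, from log-transformed counts per 10000, 2000 variable genes without the immune lists, 30 principal components and 15 neighbours, with no batch correction, and are called by their leading genes. A region was compared between groups if it had at least 30 usable spots in each of the 4 sections.

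Counts were summed over spots before any test, because spots of a section are not replicates. Each comparison used edgeR's quasi-likelihood test with TMM normalization and filterByExpr on the fitted sums, with Benjamini-Hochberg adjustment over all genes tested, and genes were called at an adjusted p under 0.05. Tumour and sham were compared over 4 whole-section sums and, per region, over 4 regional sums, with the group as the only term. Zone, border and distant tissue were fitted together over 6 sums with the section as a block, leaving 2 residual degrees of freedom. CPM values are means over sections ± SD on TMM-scaled library sizes. The SE of a log2 fold change was derived from the test, as its absolute value over the square root of the F statistic. It is only approximate where a group has few counts. For genes with 0 counts in a group the fold is a lower bound against a floor of 3 counts over the group, and for 1 to 3 counts the ratio of summed counts has an exact 95% binomial (Clopper-Pearson) interval that covers counting error only. Shifts of a list's genes against all other genes were tested with camera on log2 CPM with voom weights at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, with Benjamini-Hochberg adjustment over the lists of a comparison. List medians are also given with members without counts in a group at their bound where this changes them.

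The 38 lists were microglia, activated microglia, monocyte and macrophage, border-associated macrophage, dendritic cell, T cell, NK and cytotoxic, B and plasma cell, neutrophil, MHC class I, MHC class II, interferon response, complement, chemokine, immune checkpoint, proliferation, neural progenitor and glioma, extracellular matrix, endothelium, angiogenic endothelium, mural cell, hypoxia, glycolysis, reactive astrocyte, astrocyte, oligodendrocyte, oligodendrocyte precursor, cortical excitatory neuron, striatal neuron, interneuron, synapse, ependyma, choroid plexus, meninges, mitochondrial RNA, haemoglobin, immediate early and ribosomal protein genes. The last was set by a pattern on gene names that also matches the Rps6ka kinase genes. Named genes came from a fixed rule: per comparison the 6 called genes with the largest increases and the 6 with the largest decreases among those with an average log2 CPM of at least 5 that moved the same way in every library, skipping unnamed gene models; up to the 4 most abundant members of a list and the member with the largest change; and 34 genes named in advance, 33 of which were tested in the whole-section comparison. The text names part of these. Lists without at least 3 tested members were left out of a comparison.

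The code was tested on simulated data, in which counts were drawn for the real genes at the real depths and 200 genes were changed. In the whole-section design, over 15408 genes, 0%, 14.1% and 68.2% of genes changed 1.5-, 2- and 4-fold were recovered, and 16 of 70 calls were false. In the zone design, over 14913 genes, 37.3%, 79.1% and 97.0% were recovered, with 20 of 162 calls false. In region 1, over 11543 genes, 13.4%, 74.6% and 100% were recovered (8 of 133 calls false), and in region 4, over 9114 genes, 0%, 0% and 16.7% (1 of 11). A simulated changed list of 20 members was called in all 4 designs and 0 of 20 unchanged lists were. The simulated genes were drawn independently and the lists filled at random. The list result therefore does not cover lists whose genes move together, as genes of a cell type can. Alternatives covered DESeq2 size factors, library size only, a total count of at least 10, at least 20 counts in every library of a group, thinning to the smallest total, spots of at least 1000 UMIs, leaving out mitochondrial, ribosomal protein and haemoglobin genes, glmTreat against a fold change of 1.5, the DESeq2 Wald test, the replicate number as a block, each section left out, no section block, other zone thresholds, zone by clusters, border widths of 2 and 5 steps, distant tissue from 4 or 10 steps, regions by marker lists and resolution 1.0. For the comparisons of zone, border and distant tissue, values with 1 section left out are not refits. They are differences of log2 CPM within the other section, with a prior count added that pulls genes with few counts toward 0. A region under another definition was set beside region 1 or 4 only where it held at least 50% of that region's spots, a rule chosen after seeing the data. The tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.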

Results

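Spatial transcriptomes were measured in brain hemispheres of male C57BL/6J mice, 2 sections from PBS-injected (sham) hemispheres and 2 from hemispheres injected with GL261, a mouse glioma cell line, here carrying a fluorescent and a luciferase reporter. The mice were injected in the right striatum at 10 weeks of age, with 80000 cells in the tumour group, and the tissue was taken at day 21. Frozen sections of 10 µm lay on Visium slides, on which each barcoded spot captures RNA from a small area that can hold several cells. The sham sections held 2208 and 2673 spots with 10333238 and 10036123 unique molecular identifiers (UMIs). The tumour sections held 2327 and 2769 spots with 22126945 and 29600917. The median spot held 4136 and 2689 UMIs in the sham sections against 9555 and 10016 in the tumour sections. Spots with under 1000 UMIs made up 25.9% and 41.3% of sham spots but 3.997% and 0.686% of tumour-section spots. Mitochondrial transcripts took 17.5% and 21.2% of sham UMIs and 9.07% and 11.2% of tumour-section UMIs, and ribosomal protein transcripts 7.47% and 6.63% against 13.4% and 14.2%. Across genes, log2 CPM (counts scaled to the library total) correlated at 0.961 between the sham sections, at 0.984 between the tumour sections and at 0.828 to 0.869 between groups, where genes are not independent replicates. The labels do not state that the sections of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical. Each comparison had 2 sections per group, and fold changes are given as log2 values ± SE, where the SE is derived from the F statistic of the test.

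A compact area of dividing cells was present in each tumour section. Transcripts of 29 cell cycle genes, among them Mki67 and Top2a, set a spot's proliferation level, and 1 connected group of spots lay above the sham-based threshold of 11.4 per 10000 UMIs in each tumour section and 0 in each sham section. This zone held 952 spots (40.9% of the section) in tumour replicate 1 and 775 spots (27.99%) in tumour replicate 2. Its median levels were 27.6 and 27.4 per 10000. Distant tissue, 6 or more spots away, had medians of 0.774 and 0.518. The border, 1 to 3 spots outside the zone, held 294 and 351 spots. In an unsupervised clustering into 11 regions, 2 regions came entirely from the tumour sections. One of them, of 1142 spots, was led by Hmga2, Moxd1, Anxa1 and AI506816, and the other, of 645 spots, by Lcn2, Ccl2, Klk6, Col9a1 and Ly6c2. Of the sham spots, 774 of the 777 spots of a region led by Pmch and Hcrt, genes of lateral hypothalamic neurons, came from sham replicate 1. Another 725 of the 997 spots of a region with Pde10a and Drd2, genes of striatal neurons, among its leading genes came from sham replicate 2. Within 20% of the threshold lay 97 and 76 spots of the tumour sections.

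**Figure D1:**
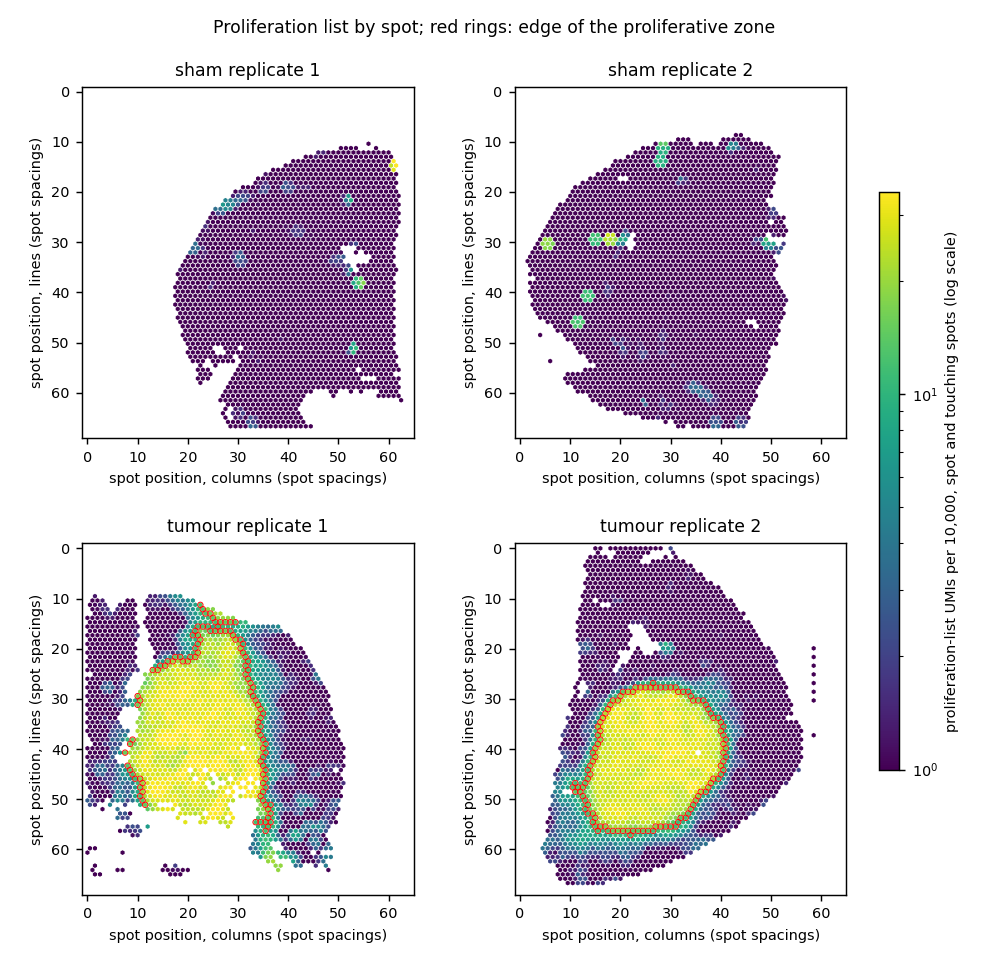
Proliferation level of every spot (UMIs of 29 cell cycle genes per 10000 UMIs, summed over a spot and the spots touching it) at its position in the 4 sections. The zone, outlined by the threshold of 11.4 per 10000, covers 952 spots in tumour replicate 1 and 775 in tumour replicate 2, and 0 in the sham sections, from which the threshold was set.

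The first comparison set whole GL261 sections against whole sham sections, to show what the injected cells and the tissue around them add to the hemisphere. Genes of antigen presentation and of the interferon response were higher in the tumour sections. All 8 genes of the MHC class II list rose, with a median of 8.15 (7.72 with the 1 member that had no sham counts at its bound). The list holds genes of the molecules that present peptides to CD4 T cells, such as H2-Aa, and genes that serve them. The class II invariant chain gene Cd74 averaged 1756 ± 606 CPM (SD, n = 2) in tumour sections and 4.17 ± 0.593 CPM in sham sections, a log2 fold change of 8.71 ± 0.38. H2-Aa differed by 8.51 ± 0.37. All 14 MHC class I genes rose (median 5.34), including H2-K1 (4.96 ± 0.24) and H2-D1 (4.55 ± 0.22), near-identical class I genes whose reads can be shared between copies. All 28 interferon response genes rose (median 5.82). Cxcl10 and Cxcl9, interferon-induced chemokines that attract lymphocytes, differed by 8.96 ± 0.50 and 8.77 ± 0.79, with Cxcl10 at 546 ± 175 CPM against 1.10 ± 0.714. In each of these 3 lists the count adjusted over the list alone was the same. Camera gave adjusted p = 1.83e-05, 4.73e-09 and 3.36e-15, and adjusted p = 0.575 with an estimated correlation for each.

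Genes of the myeloid and lymphocyte lists rose too, in spots that mix cells, so the cells that carry them were not resolved. Of the monocyte and macrophage list 16 of 20 genes rose (18 adjusted over the list alone), among them Lyz2, the macrophage lysozyme gene (5.18 ± 0.22), the monocyte chemokine receptor gene Ccr2 (6.11 ± 0.45) and Ly6c2 (8.07 ± 0.65), a close paralog of Ly6c1. Sham sections held 2 Ccr2 UMIs, giving a ratio of 72.6 (95% counting interval 19.97 to 601), and 3 Ly6c2 UMIs (ratio 269, 91.8 to 1303). Plac8, of the same list, had the largest log2 fold change among well-expressed called genes, 9.25 ± 0.60, from 3550 UMIs against 2 (ratio 633, 175 to 5230). Of activated microglia genes 13 of 18 rose (14 adjusted over the list alone), led by Gpnmb, also a leading gene of the region led by Hmga2 (8.94 ± 0.21; 864 ± 55.5 against 1.75 ± 0.350 CPM). Of border-associated macrophage genes 5 of 9 (6 adjusted over the list alone), with Ms4a7 at 4.30 ± 0.32 and Ccl8 at 6.01 ± 0.31. T cell genes rose in 12 of 16 cases (also 12 adjusted over the list alone; median 3.89 with 3 members at their bound). NK and cytotoxic genes rose in 8 of 10 (10 adjusted over the list alone; median 5.78 with 4 at their bound), with Ccl5 at 8.66 ± 0.88. Complement genes rose in 10 of 11 cases (C4b 5.20 ± 0.43), chemokine genes in 13 of 16 and immune checkpoint genes in 9 of 12, with the PD-L1 gene Cd274 at 4.33 ± 0.61. Adjusted over the list alone the counts were 10, 13 and 9 higher, with 1 chemokine gene lower. For these 8 lists camera's adjusted p ranged from 3.30e-08 (monocyte and macrophage) to 0.00540 (immune checkpoint), and with an estimated correlation they lay at adjusted p = 0.575 to 0.695. Of the 14 microglia genes, 7 were higher and 1 lower (8 and 1 adjusted over the list alone) and the list was not called (median 0.71, adjusted p = 0.0977). Tmem119 and Csf1r rose by 1.59 ± 0.13 and 1.01 ± 0.13, while P2ry12, the purinergic receptor of resting microglia, stood at -0.55 ± 0.19 (adjusted p = 0.0841).

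Astrocyte, dividing and matrix genes separated the groups as well. Reactive astrocyte genes rose in 10 of 12 cases (11 adjusted over the list alone), with Vim, an intermediate filament gene, at 3.96 ± 0.13 and Gfap at 1.98 ± 0.52. The iron-carrier-binding protein gene Lcn2 had 0 UMIs in both sham sections and was at least 241-fold higher in tumour sections, against a floor of 3 counts over the sham group. Homeostatic astrocyte genes fell in 7 of 12 cases (9 adjusted over the list alone), among them Ntsr2 (-1.27 ± 0.17). All 29 proliferation genes rose (also 29 adjusted over the list alone; median 5.17). So did 9 of 18 extracellular matrix genes (11 adjusted over the list alone) and 5 of 10 oligodendrocyte precursor genes (7 adjusted over the list alone), with the lineage factors Sox10 at 2.52 ± 0.41 and Olig2 at 2.26 ± 0.24. Outside the lists, the imprinted non-coding RNA H19 differed by 8.91 ± 0.18. Synapse genes fell in 8 of 12 cases (10 adjusted over the list alone), with the postsynaptic scaffold gene Dlg4 at -1.17 ± 0.15, and interneuron genes in 4 of 8 (also 4 adjusted over the list alone), with Pvalb at -1.48 ± 0.13 and Sst at -1.15 ± 0.14. The 6 largest decreases among well-expressed genes were Pcp4 (-2.01 ± 0.16), Lars2 (-1.94 ± 0.47), Rora (-1.88 ± 0.46), Spock3 (-1.79 ± 0.26), Ctxn2 (-1.72 ± 0.45) and Btbd17 (-1.68 ± 0.12). Mitochondrial RNA fell in 10 of 13 genes (12 adjusted over the list alone; median -1.10), and ribosomal protein genes, a family with many near-identical pseudogene copies, rose in 60 of 92 cases and fell in 3 (70 and 3 adjusted over the list alone). The oligodendrocyte list was called lower by camera (median -1.07, adjusted p = 0.00575) with 0 of its 12 genes called. With an estimated correlation these lists lay at adjusted p = 0.575 to 0.746.

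In all, edgeR's quasi-likelihood test called 5128 of 15663 genes in the whole-section comparison, 3276 higher and 1852 lower, at a Benjamini-Hochberg adjusted p under 0.05. The adjusted p of the called genes named above ranged from 0.00134 (H19) to 0.0448 (Gfap). Of 33 genes fixed by name in advance, 26 were called higher, 0 lower, and Apoe, Arg1, Cd4, Mrc1, P2ry12, Spp1 and Vegfa were not called. Camera called 16 of 38 lists higher and 5 lower. With an estimated correlation 0 lists were called, with 0 at an unadjusted p under 0.05 and a lowest adjusted p = 0.575, while fry, which asks whether a list's genes move one way on balance, called 13 higher and 1 lower. Lists not called by camera were dendritic cell (adjusted p = 0.124), B and plasma cell (0.290), neutrophil (0.415), neural progenitor and glioma (0.316), endothelium (0.971), angiogenic endothelium (0.415), mural cell (0.0524), hypoxia (0.971), glycolysis (0.167), cortical excitatory neuron (0.109), striatal neuron (0.162), ependyma (0.598), choroid plexus (0.910), meninges (0.807), haemoglobin (0.464) and immediate early (0.971). Of these 16 lists, dendritic cell and neural progenitor and glioma had 4 genes each called higher, angiogenic endothelium 3, glycolysis and immediate early 2 each, and B and plasma cell, neutrophil and endothelium 1 each. Mural cell and glycolysis had 3 genes each called lower, endothelium and cortical excitatory neuron 2 each, and hypoxia and angiogenic endothelium 1 each, and the other counts were 0. Adjusted over the list alone, 2 counts differed, with 4 glycolysis genes lower and 0 immediate early genes higher. The choroid plexus median was 0.71 although its test pointed lower, the glycolysis mean was 0.20 beside a median of -0.29, and the immediate early mean was 0.01 beside a median of -0.28. Cd4 stood at -0.67 ± 1.09, and at 2.47 without sham replicate 2, whose section held 18.3 CPM of Cd4 against 1.10 in sham replicate 1. Cxcl9 had 0 counts in sham replicate 1, so its fold rests on sham replicate 2. Without that section the fit gave 13.96 against 0 sham counts, which is not an estimate of the fold. Ctxn2 and Rora stood at -0.98 and -1.05 without sham replicate 1, and Lars2 and Gfap at -1.08 and 1.40 without sham replicate 2. The count of called genes dropped to 844 without tumour replicate 1 and to 1255 without tumour replicate 2. Of these, 838 and 1208 were higher and 6 and 47 lower. Without a sham section 7105 (replicate 1) and 6972 (replicate 2) genes were called, 3978 and 3917 of them higher and 3127 and 3055 lower. With library size as the only scaling, which puts the median over all genes at 0.12 in place of -0.0259, 77.7% of calls were higher, against 63.9% with TMM.

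Within the tumour sections, the zone of dividing cells was compared with distant tissue of the same section. Among called genes with an average log2 CPM of at least 5, those higher in the zone were led by Cdkn2a, a cell cycle inhibitor gene (6.52 ± 0.29), AI506816 (6.27 ± 0.23), Gpnmb (6.10 ± 0.28), Csprs (6.10 ± 0.19), the chromatin factor gene Hmga2 (6.03 ± 0.20) and H19 (5.93 ± 0.22). Monocyte and macrophage genes rose in 18 of 20 cases and fell in 1 (19 and 1 adjusted over the list alone), with Lyz2 at 4.52 ± 0.24 and Tgfbi at 4.51 ± 0.20. MHC class II genes rose in all 8 cases, from 375 ± 190.4 to 3391 ± 662 CPM for Cd74 (SD, n = 2), MHC class I genes in all 14 and interferon response genes in all 28, with Cxcl10 at 5.49 ± 0.38. T cell genes rose in 16 of 18 cases, with Cd3g at 4.11 ± 0.41 and Cd8a at 5.12 ± 0.56 (139 UMIs in the zones and 3 in distant tissue, a ratio of 38.7 with a counting interval of 12.98 to 190). NK and cytotoxic genes rose in 9 of 10 cases, with the granzyme genes Gzma and Gzmb at 4.46 ± 0.21 and 4.59 ± 0.25 and Ccl5 at 4.51 ± 0.42. In each of the last 5 lists the count adjusted over the list alone was the same. Immune checkpoint genes rose in 12 of 13 cases (Cd274 3.34 ± 0.30, Lgals9 3.97 ± 0.23), complement genes in 10 of 11, chemokine genes in 14 of 16 and activated microglia genes in 17 of 18 (Lgals3 4.80 ± 0.18, Spp1 1.45 ± 0.21), also 12, 10, 14 and 17 adjusted over the list alone. The fractalkine gene Cx3cl1, a neuronal chemokine gene, fell by 3.11. Camera's adjusted p for these 10 lists ranged from 3.25e-10 to 0.0107, and with an estimated correlation they lay at adjusted p = 0.459 to 0.588.

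Microglial genes did not move together between zone and distant tissue. Of the 14 microglia genes 5 were higher and 5 lower (6 and 6 adjusted over the list alone; median -0.01, adjusted p = 0.719). Tmem119 was higher by 1.52 ± 0.15 and Csf1r by 0.69 ± 0.11, while P2ry12 was lower (-1.27 ± 0.21). Oligodendrocyte precursor genes rose in 7 of 10 cases and fell in 1 (also 7 and 1 adjusted over the list alone), with Olig2 at 3.53 ± 0.12, Sox10 at 3.49 ± 0.13 and Gpr17 at 2.60 ± 0.13. Oligodendrocyte genes fell in 11 of 12 cases (also 11 adjusted over the list alone), with the myelin gene Mbp at -2.06 ± 0.20. Astrocyte genes fell in 11 of 12 cases, with the glutamate transporter gene Slc1a2 at -3.21 ± 0.12, cortical excitatory neuron genes in all 11, with Camk2a at -4.16 ± 0.16, interneuron genes in all 8 and synapse genes in all 12, with Snap25 at -4.26 ± 0.27. Striatal neuron genes fell in 7 of 13 cases and choroid plexus genes in 7 of 8; in these 6 lists the count adjusted over the list alone was the same. At an average log2 CPM of at least 5, the largest decreases among called genes were those of Calb2, the calretinin gene (-5.44 ± 0.77), Rtn4r (-4.89 ± 0.39), the synaptic zinc transporter gene Slc30a3 (-4.86 ± 0.36), Nrn1 (-4.82 ± 0.40), the cholecystokinin gene Cck (-4.80 ± 0.55) and Adcy1 (-4.63 ± 0.49). Within the neural progenitor and glioma list, 6 genes rose and 5 fell, also 6 and 5 adjusted over the list alone, and the list was not called (adjusted p = 0.332); Cd44, Nes and Sox2 were higher by 4.86 ± 0.15, 3.32 ± 0.17 and 2.08 ± 0.14. Mitochondrial RNA fell in all 13 genes (also 13 adjusted over the list alone; median -2.90). Over the called lists of this paragraph camera's adjusted p ranged from 1.51e-06 (mitochondrial RNA) to 0.0476 (striatal neuron), and with an estimated correlation they lay at adjusted p = 0.459 to 0.588. EdgeR's quasi-likelihood test called 11690 of 15279 genes, 5734 higher in the zone and 5956 lower, and of 33 genes fixed by name 27 were higher, Apoe (-0.60 ± 0.14) and P2ry12 lower, and Cx3cr1, Gfap, Mrc1 and Vegfa not called. Camera called 15 lists higher, 1 of them the proliferation list that sets the zone, and 8 lower, fry 16 and 6, and with an estimated correlation 0 lists were called, 1 having an unadjusted p under 0.05. The called genes named for this comparison had adjusted p = 1.78e-07 (AI506816) to 0.00358 (Apoe). Without tumour replicate 1 Calb2 and Apoe stood at -3.36 and -0.38. The 6 sums leave 2 residual degrees of freedom, and Csf1r stood at -0.17 with a zone threshold of 27.95 per 10000.

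**Figure D2:**
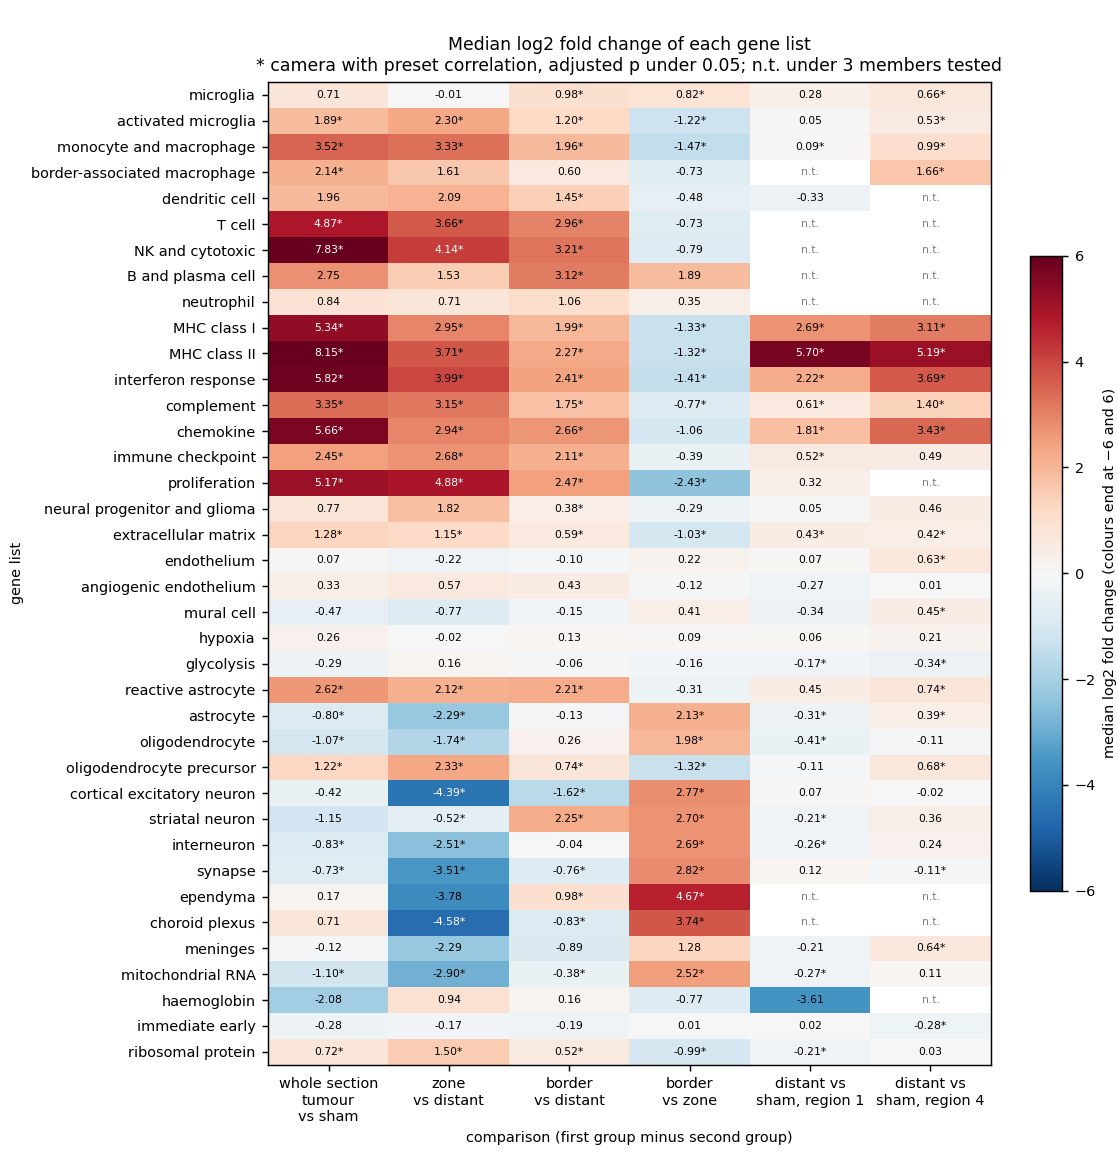
Median log2 fold change of the genes of each list (colour, limited at 6 in either direction) in the whole-section, zone, border and region comparisons. MHC class II genes reach 8.15 in whole sections and 5.70 in distant tissue of region 1, and synapse genes -3.51 in the zone against distant tissue.

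The border, 1 to 3 spots outside the zone, was compared with distant tissue to show how tissue next to the zone differs from tissue farther off. The border was not free of zone transcripts: Hmga2 and H19 averaged 9.44 and 75.1 CPM there against 1.85 and 14.2 in distant tissue. With the threshold from sham spots of at least 1000 UMIs, the zone held 1275 and 1073 spots in place of 952 and 775. Part of the border may thus belong to the zone, and increases in the border were not separated from zone content. Brain structure and distance are confounded here: 73 and 84 border spots but 19 and 8 distant spots lay in the region with Pde10a and Drd2, and 226 and 271 distant spots but 15 and 7 border spots in a region led by Vip and Lamp5. Reactive astrocyte genes rose in 10 of 12 cases (also 10 adjusted over the list alone), with Gfap at 2.34 ± 0.23 (937 ± 109 against 189 ± 69.8 CPM; SD, n = 2), the acute-phase gene Serpina3n at 3.30 ± 0.16, Lcn2 at 3.84 ± 0.22 and Vim at 2.68 ± 0.20. Microglia genes rose in 8 of 14 cases (10 adjusted over the list alone), with Tmem119 at 1.14 ± 0.16, the fractalkine receptor gene Cx3cr1 at 1.10 ± 0.14 and Csf1r at 1.00 ± 0.11, and P2ry12 stood at 0.11 ± 0.22 (adjusted p = 0.750), with opposite signs in the sections (0.51 without tumour replicate 1 and -0.41 without tumour replicate 2). Complement genes rose in 10 of 11 cases, with C3 at 3.89 ± 0.33, C4b at 2.33 ± 0.20 and C1qa at 1.73 ± 0.11, and MHC class II genes in all 8, with Cd74 at 2.02 ± 0.18 and H2-Aa at 2.11 ± 0.19. MHC class I genes rose in all 14 cases and interferon response genes in all 28, among them Cxcl9 (3.60 ± 0.37); in these 4 lists the count adjusted over the list alone was the same. Among called genes with an average log2 CPM of at least 5, the others with the largest increases were Igkc, an immunoglobulin light chain gene (4.11 ± 0.29), the secreted protease gene Klk6 (3.72 ± 0.15) and the interferon-inducible Ubd (3.58 ± 0.53). Camera's adjusted p for these 6 lists ranged from 9.62e-23 to 9.98e-06 (microglia), with adjusted p = 0.169 with an estimated correlation, or 0.438 for microglia.

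Lymphoid and neuronal genes also differed between border and distant tissue. T cell genes rose in 13 of 18 cases (15 adjusted over the list alone), with Cd3g at 3.38 ± 0.47. NK and cytotoxic genes rose in 8 of 10 (9 adjusted over the list alone), with Gzma at 3.42 ± 0.25, and B and plasma cell genes in 4 of 7 (7 adjusted over the list alone). The B cell genes Ms4a1 (4.60 ± 1.05; 27 UMIs against 2, ratio 35.3 with a counting interval of 8.87 to 306) and Cd79b (3.12 ± 0.94) rested on tumour replicate 1: without it they stood at -0.43 and -0.56 and the list median at -0.12. Camera gave these 3 lists adjusted p = 1.42e-06, 8.29e-05 and 0.00112, and adjusted p = 0.476, 0.435 and 0.476 with an estimated correlation. All 13 striatal neuron genes rose (also 13 adjusted over the list alone), with Drd2 at 3.03 ± 0.22, Penk at 2.25 ± 0.17 and Ppp1r1b at 2.01 ± 0.11, and 10 of 11 cortical excitatory neuron genes fell (11 adjusted over the list alone), with Neurod2 at -1.81 ± 0.54. Synapse genes fell in all 12 cases (also 12 adjusted over the list alone), with Snap25 at -1.28 ± 0.24. These 3 lists had camera adjusted p = 1.76e-16, 2.05e-07 and 2.00e-08, and adjusted p = 0.169, 0.451 and 0.332 with an estimated correlation. Among called genes with an average log2 CPM of at least 5, the largest decreases, besides Neurod2, were those of Calb2 (-2.14 ± 0.66), Cck (-2.04 ± 0.49), Kcnab3 (-1.98 ± 0.34), Ptgds (-1.96 ± 0.33) and Rtn4r (-1.93 ± 0.35). Several of these differed between the sections: without tumour replicate 1 Calb2 and Cd3g stood at -0.27 and 2.19, and without tumour replicate 2 Neurod2, Cck, Kcnab3, Rtn4r and Snap25 at -0.67, -0.87, -1.22, -1.23 and -0.81. Other lists called higher were activated microglia, monocyte and macrophage, dendritic cell, chemokine, immune checkpoint, neural progenitor and glioma, extracellular matrix, oligodendrocyte precursor, ependyma and ribosomal protein, with medians of 0.38 (neural progenitor and glioma) to 2.66 (chemokine). Those called lower were choroid plexus (-0.83, and 0.37 without tumour replicate 2) and mitochondrial RNA (-0.38). Camera's adjusted p for these 12 lists ranged from 1.94e-20 (ribosomal protein) to 0.0367 (dendritic cell), with adjusted p = 0.169 (activated microglia) to 0.611 (choroid plexus) with an estimated correlation. EdgeR's quasi-likelihood test called 3729 of 15279 genes, 1997 higher in the border and 1732 lower, with 65.2% of calls higher under library size alone against 53.6% with TMM. Camera called 21 lists higher, 1 of them the proliferation list that sets the zone, and 4 lower, fry 12 and 0, and with an estimated correlation 0 lists were called, 8 having an unadjusted p under 0.05. Called genes named for this comparison had adjusted p = 3.61e-05 (Klk6) to 0.0470 (Calb2). The count follows the zone threshold: it was 95 at 1.45 per 10000 (72 higher) and 10062 at 27.95 (4849 higher), and 323 (268 higher) at 2.997, a threshold taken from sham spots of at least 1000 UMIs (chosen after seeing the data), 1119 (921 higher) against a fold change of 1.5 and 2425 (1528 higher) by DESeq2. At 27.95 per 10000 Cx3cr1, Aqp4, Ppp1r1b and Cd79b, and at 1.45 Calb2 and Cd3g, stood on the other side of 0, at -0.34, -0.28, -0.14, -0.44, 1.70 and -0.11.

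Set against the zone, the border held more transcripts of brain cells and fewer of the genes that marked the zone. Among called genes with an average log2 CPM of at least 5, those with the largest increases were Ttr, the transthyretin gene of the choroid plexus (3.50 ± 1.28, 2661 ± 3609 against 90.3 ± 102 CPM), the neuropeptide gene Cartpt (3.47 ± 0.35), the cannabinoid receptor gene Cnr1 (3.45 ± 0.14), Nnat (3.45 ± 0.32), Ntsr2 (3.44 ± 0.14) and Cacng2 (3.35 ± 0.19). At the same expression limit, the largest decreases were those of Hmga2 (-3.60 ± 0.18), H19 (-3.49 ± 0.19), Moxd1 (-3.44 ± 0.22), AI506816 (-3.41 ± 0.20), Csprs (-3.33 ± 0.16) and Sec16b (-3.25 ± 0.19). Gfap was higher in the border (1.97 ± 0.22), but the reactive astrocyte list went both ways, with 4 of 12 genes higher and 6 lower (also 4 and 6 adjusted over the list alone) and no call of the list (adjusted p = 0.423). Microglia genes were higher in 10 of 14 cases and lower in 1 (also 10 and 1 adjusted over the list alone), with P2ry12 at 1.38 ± 0.23, Cx3cr1 at 1.10 ± 0.14 and Crybb1 at 2.07 ± 0.30. Monocyte and macrophage genes were lower in 16 of 20 cases and higher in 1 (also 16 and 1 adjusted over the list alone), with Lyz2 at -2.33 ± 0.22 and Tgfbi at -2.54 ± 0.19. MHC class II genes were lower in 7 of 8 (also 7 adjusted over the list alone), with Cd74 at -1.25 ± 0.17. Interferon response genes were lower in 25 of 28 cases (Cxcl10 -2.18 ± 0.32), MHC class I genes in 13 of 14, complement genes in 8 of 11 (C4b -1.11 ± 0.19) and activated microglia genes in 13 of 18 (Gpnmb -3.22 ± 0.24), with the same counts adjusted over the list alone. Striatal neuron genes were higher in all 13 cases, synapse, astrocyte and oligodendrocyte genes in all 12 each, interneuron genes in all 8 and cortical excitatory neuron genes in 10 of 11, again with the same counts adjusted over the list alone. Camera's adjusted p for these 13 lists ranged from 5.34e-08 (striatal neuron) to 0.0470 (microglia), and was 0.724 with an estimated correlation for each.

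Lymphocyte lists were not called between border and zone, although single genes were. Of 10 NK and cytotoxic genes 5 were lower in the border (also 5 adjusted over the list alone), among them Gzma (-1.04 ± 0.17), Gzmb (-1.36 ± 0.20), Ccl5 (-1.31 ± 0.37) and Klrk1 (-1.77 ± 0.31), with a list median of -0.79 (camera adjusted p = 0.0939). At a zone threshold of 27.95 per 10000 these 4 genes stood at 0.0933, 0.0924, 0.0119 and 0.20. Of 18 T cell genes 1 was higher, Cd4 (2.09 ± 0.29; 20.6 ± 5.63 against 4.85 ± 0.235 CPM; adjusted p = 2.82e-04), and 1 lower, Lck (-1.78 ± 0.35; adjusted p = 0.00206), also 1 and 1 adjusted over the list alone. Cd8a stood at -0.77 ± 0.39, Cd3e at -0.94 ± 0.62 and Cd3g at -0.73 ± 0.33, with adjusted p = 0.115, 0.206 and 0.0761. Without tumour replicate 2 Ccl5 and Lck stood at -0.37 and -1.11, and Cd8a, Cd3e and Cd3g at -0.25, 0.01 and -0.18. The T cell list had a median of -0.73 (adjusted p = 0.356) and the B and plasma cell list one of 1.89 (adjusted p = 0.185), with 3 of 7 genes called higher and 1 adjusted over the list alone. Its members Ighm and Ms4a1 stood at 1.89 ± 0.38 (adjusted p = 0.00240) and 2.10 ± 0.75 (adjusted p = 0.0357), Ms4a1 at -0.77 without tumour replicate 1. EdgeR's quasi-likelihood test called 9963 of 15279 genes, 5059 higher in the border and 4904 lower, and 1805 at a zone threshold of 27.95 per 10000, with 1634 higher and 171 lower. Camera called 10 lists higher and 10 lower, 1 of them the proliferation list that sets the zone, fry 5 and 2, and with an estimated correlation 0, with 0 at an unadjusted p under 0.05. Genes called and named for this comparison had adjusted p = 1.63e-06 (Cnr1) to 0.0389 (Ttr). At a zone threshold of 1.45 per 10000 Cd4, Cx3cr1 and Gfap stood at -0.13, -0.23 and -0.46.

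Levels of the lists were then followed by distance from the edge of the zone, per 10000 UMIs and without a test, since 2 sections are too few. Microglia genes were highest around the edge of the zone, at 10.1 in tumour replicate 1 and 8.73 in tumour replicate 2 in the 3 outermost spots inside it and at 9.91 and 9.62 in the first 3 spots outside. They stood at 4.16 and 3.36 in spots 8 or more inside, at 5.05 and 3.64 in spots 11 or more outside and at 3.40 and 3.64 in the sham sections. Reactive astrocyte genes reached 27.1 and 28.1 just inside the edge and 22.0 and 20.1 just outside it, with 2.87 and 2.24 far outside and 2.12 and 1.197 in sham sections. MHC class II genes stood at 85.5 and 56.5 deep inside the zone, at 43.4 and 20.4 just outside and at 5.84 and 3.10 far outside, where sham sections had 0.207 and 0.208. Interferon response genes stood at 129 and 103 deep inside, 54.2 and 31.2 just outside and 6.20 and 2.59 far outside, against 0.860 and 0.951 in sham sections. Monocyte and macrophage genes stood at 63.0 and 52.1 deep inside and 3.95 and 2.14 far outside, against 1.49 and 1.46 in sham sections. These gradients depend on the zone threshold: from just outside to far outside, reactive astrocyte, MHC class II, interferon response and monocyte and macrophage genes fell off by ratios of 8.30, 7.01, 10.4 and 5.81, but of 3.10, 3.49, 3.66 and 1.97 at a threshold of 1.45 per 10000. The microglia ratio of edge to deep inside was 2.51, and 1.60 at that threshold. Striatal neuron genes stood at 18.4 and 44.8 just outside the zone and at 6.05 and 4.22 far outside, and at 7.46 and 35.0 in the sham sections, so tissue beside the zone, tissue far from it and the sham sections differed in the brain structures they held.

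**Figure D3:**
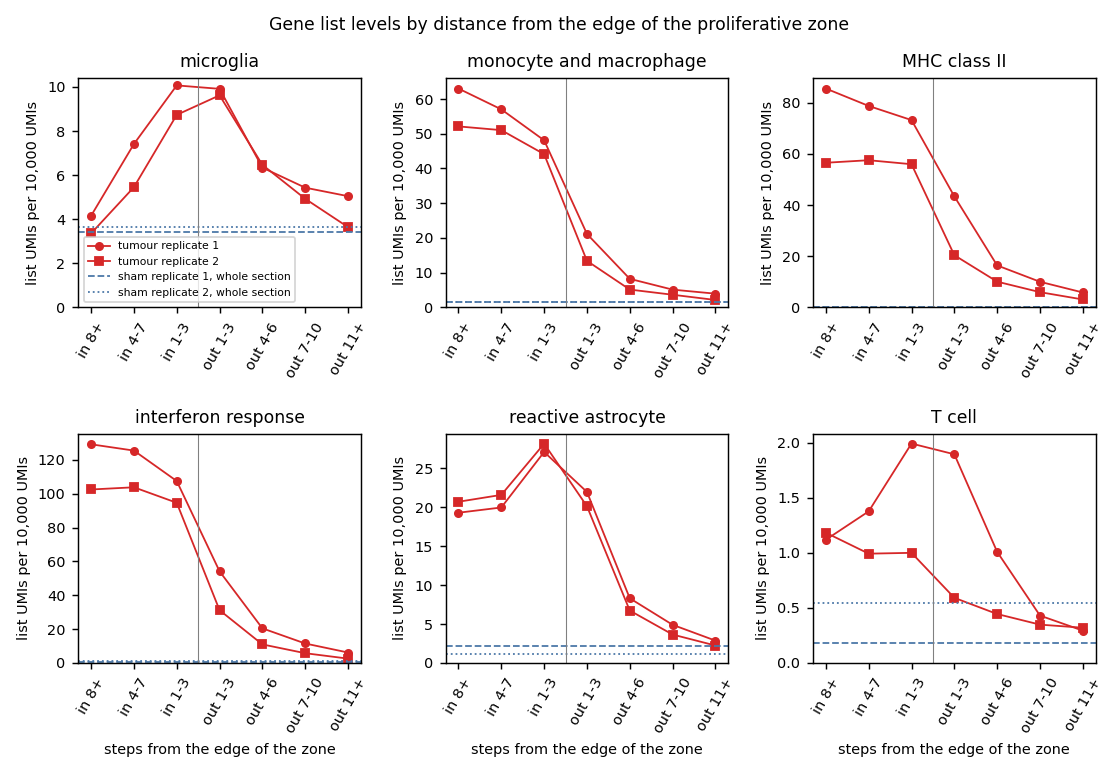
List UMIs per 10000 UMIs against distance from the edge of the zone in spots, one line per tumour section, with the sham sections' levels for comparison. The microglia list is highest around the edge, with 10.1 and 8.73 just inside and 9.91 and 9.62 just outside, while MHC class II and interferon genes fall off from inside to outside, less steeply at lower zone thresholds.

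**Figure D4:**
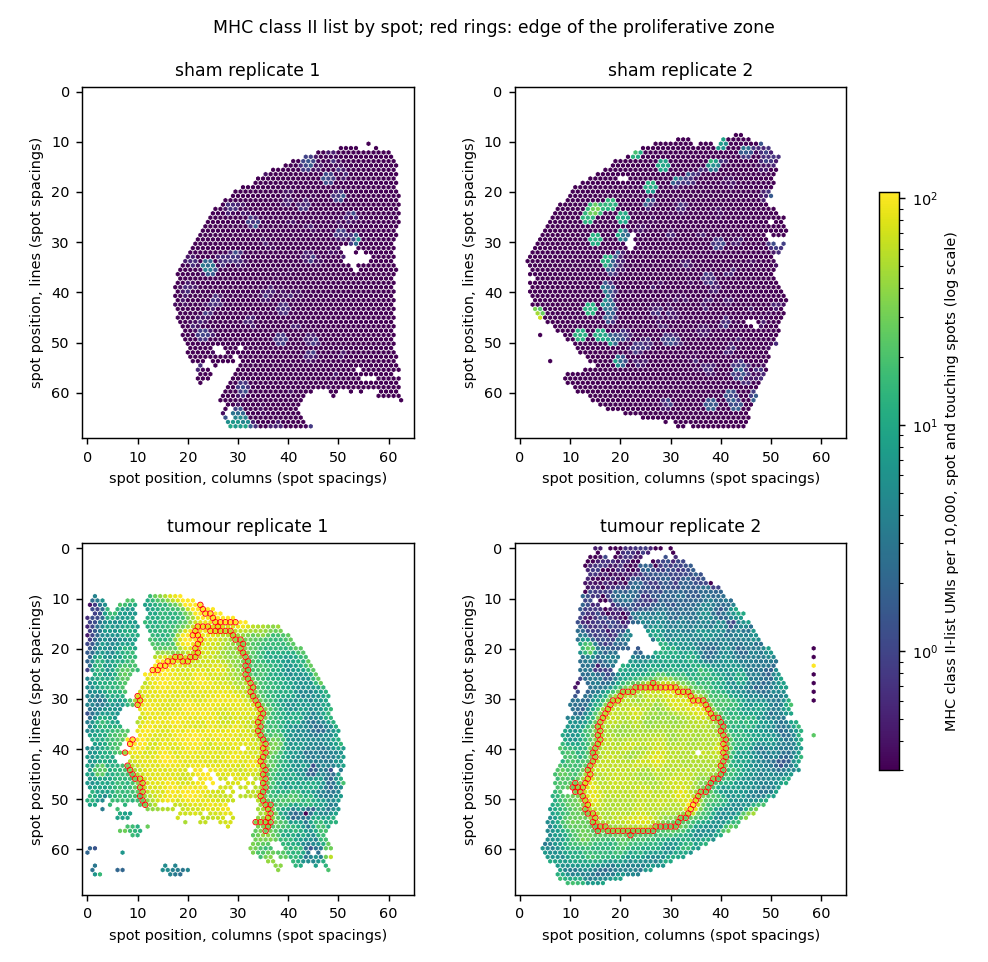
Level of the 8 MHC class II genes (UMIs per 10000 UMIs) at every spot of the 4 sections. Sham sections average 0.207 and 0.208, and tumour-section spots 11 or more from the zone 5.84 and 3.10.

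Distant tissue of the tumour sections was compared with sham tissue within regions set by the clustering, to ask whether tissue away from the zone also differed. Spots of 1 region can still differ in makeup between sections. Of 11 regions, 2 had at least 30 usable spots in each of the 4 sections. Region 1, led by Myl4, Vxn, Kcnab3, Satb1 and Pvalb, had 128 and 476 sham spots and 247 and 529 distant spots. There, MHC class II genes were higher by a median of 5.70, with 4 of 6 called (5 adjusted over the list alone). Cd74 averaged 314 ± 156 CPM in distant tissue and 2.46 ± 0.847 in sham tissue (SD, n = 2), a log2 fold change of 7.21 ± 0.44, and H2-Eb1 and H2-Ab1 differed by 5.73 ± 0.47 and 5.67 ± 0.55. H2-Aa differed by 8.15 ± 0.62, from 515 UMIs against 1 (ratio 309, counting interval 55.2 to 12214). MHC class I genes rose in 9 of 14 cases (13 adjusted over the list alone), with H2-D1 at 2.79 ± 0.17, H2-K1 at 2.59 ± 0.19 and B2m at 2.10 ± 0.20. Interferon response genes rose in 11 of 23 (21 adjusted over the list alone), with Ifi27l2a at 5.29 ± 0.54, Igtp at 2.84 ± 0.41 and Bst2 at 2.56 ± 0.36. The complement gene C4b differed by 4.66 ± 0.53, Ifitm3 by 1.85 ± 0.30 and Gpnmb by 4.07 ± 0.55. The chemokine genes Cxcl10 (4.86 ± 0.83) and Ccl5 (5.56 ± 1.16) rose from 2 and 1 sham UMIs, with ratios of 28.5 (7.67 to 238) and 49.7 (8.69 to 1988). Camera's adjusted p was 2.26e-12 for class II, 4.16e-26 for class I and 8.58e-25 for interferon response genes, and 0.386 for each with an estimated correlation.

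Other genes were lower in distant tissue of region 1. Among called genes with an average log2 CPM of at least 5, the largest decreases were those of Gstp1, a detoxifying enzyme gene (-1.42 ± 0.22), Erh (-1.26 ± 0.23), S100a1 (-1.06 ± 0.15), the myelin gene Mobp (-1.05 ± 0.23), the neuropeptide gene Cort (-1.05 ± 0.21) and Tst (-0.94 ± 0.19). Sst (-0.91 ± 0.16), the water channel gene Aqp4 (-0.91 ± 0.19) and the microglial Fcrls (-1.65 ± 0.32, at a log2 CPM of 4.22) were lower too. Gfap, Tmem119 and Lyz2 stood at 0.81 ± 0.29, 0.65 ± 0.24 and 1.13 ± 0.32, with adjusted p = 0.281, 0.294 and 0.133, and Gfap at -0.01 without sham replicate 2. Mobp stood at -0.58 without sham replicate 1, and Erh at -0.59 without sham replicate 2. Gpnmb, Ifi27l2a and Cxcl10 had 0 counts in sham replicate 1 and stood at 8.67, 9.90 and 8.21 without sham replicate 2, and Ccl5, with 0 counts in sham replicate 2, at 8.55 without sham replicate 1 and 2.98 without sham replicate 2. All of these but the 2.98 were fitted against 0 sham counts and are not estimates of the fold. EdgeR's quasi-likelihood test called 78 of 11777 genes, 48 higher and 30 lower, and of 19 genes fixed by name 5 were called, all higher. Camera called 8 of 31 lists higher and 7 lower: besides the 3 above, complement, chemokine, monocyte and macrophage, immune checkpoint and extracellular matrix were higher, and astrocyte, oligodendrocyte, interneuron, striatal neuron, glycolysis, mitochondrial RNA and ribosomal protein lower, with medians between -0.41 and -0.17. For these 12 further lists camera's adjusted p ranged from 2.96e-09 (mitochondrial RNA) to 0.0446 (immune checkpoint). With an estimated correlation the 15 lists had adjusted p = 0.386 to 0.567 and 0 were called, 1 having an unadjusted p under 0.05, and fry called 0. Called genes named for region 1 had adjusted p = 3.21e-08 (Cd74) to 0.0423 (Mobp). Without sham replicate 2 the medians of the monocyte and macrophage, extracellular matrix, striatal neuron and interneuron lists stood at -0.47, -0.07, 0.01 and 0.09. With library size as the only scaling, which puts the median over all genes at 0.12 in place of 0.00359, 42 genes were called, 92.9% of them higher against 61.5% with TMM. DESeq2, whose filter set 10731 genes aside, called 26, of which 6 were higher and 20 were shared. The balance of higher and lower calls depended on the setting: 184 and 198 without sham replicate 1, 227 and 312 without sham replicate 2, and 84 and 79 with a total count of at least 10. No gene (0) was called in a region set by the cortical excitatory neuron list, which held 86.4% of region 1 and of which region 1 made up 35.8%.

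**Figure D5:**
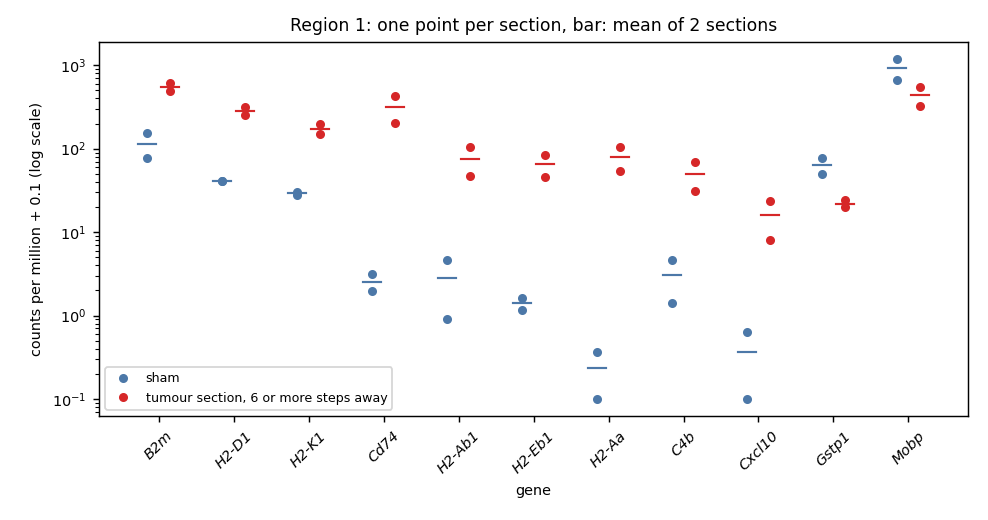
CPM (log axis, 0.1 added) of named genes in region 1, one point per section. Cd74 averages 314 in distant tissue of the tumour sections and 2.46 in sham sections, and the sections of the 2 groups do not overlap for it.

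Region 4, led by Ptgds, Cabp7, Wipf3, Gabra5 and Neurod6, gave no called gene. EdgeR's quasi-likelihood test called 0 of 9586 genes, with 221 at an unadjusted p under 0.05, and DESeq2 called 21, all higher. At resolution 1.0 a region that holds 68.8% of region 4, with 93.8% of its spots inside it, gave 24 called genes, all higher. That region, led by Ptgds, Myoc, Slc6a20a and Mgp, had 128 spots in sham replicate 1, where region 4 had 338. In sham replicate 2 and tumour replicates 1 and 2 it had 211, 174 and 163, where region 4 had 211, 160 and 213. The makeup of region 4 thus differed between sections, which the comparison does not separate from the group. Mgp, of the meninges list, averaged 412 ± 507.5 CPM (SD) in sham tissue of region 4. The region set by the cortical excitatory neuron list, which held 83.7% of region 4, gave 0. In region 4 itself Cd74 stood at 5.56 ± 0.84, H2-Aa at 5.29 ± 0.89, the interferon-induced Isg15 at 4.90 ± 1.08, C4b at 2.52 ± 0.52, Gfap at 1.57 ± 0.41 and the microglia and macrophage gene Aif1 at 1.60 ± 0.51, each with an adjusted p of 1. Adjusted over the list alone, 5 of 6 class II, 9 of 9 class I and 16 of 17 interferon response genes were called higher. Camera called 16 of 29 lists higher, with medians up to 5.19 (class II), 3.69 (interferon response) and 3.43 (chemokine), and 3 lower (glycolysis, synapse and immediate early). Over the called lists camera's adjusted p ranged from 7.24e-14 to 0.0291. With an estimated correlation these lists had adjusted p = 0.548 to 0.611 and 0 were called, with 0 at an unadjusted p under 0.05, and fry called 0. Isg15, Gfap and Aif1 stood at 2.97, 0.85 and 0.83 without tumour replicate 1. The count of genes was 53 without sham replicate 1, 33 without sham replicate 2, 2 without tumour replicate 1 and 25 without tumour replicate 2. Without sham replicate 1 the extracellular matrix, endothelium, mural cell, meninges and astrocyte lists had medians of -0.59, -0.22, -0.40, -0.31 and -0.06. Without tumour replicate 1 extracellular matrix, endothelium, mural cell and synapse stood at -0.38, -0.02, -0.11 and 0.02, and without tumour replicate 2 immediate early stood at 0.07. A test of the difference between the regions' effects called 0 of 11520 genes, with 239 at an unadjusted p under 0.05, so the effects of region 1 and region 4 were not shown to differ.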

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

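The zone threshold taken from sham spots of at least 1000 UMIs was the only alternative chosen after the result was seen. Named genes kept their direction and, where tested, their side of the threshold in 3157 of the settings tried. Another 167 kept the direction but were no longer called, 33 became called and 29 changed direction. A further 2, not called in the main setting, also changed direction without tumour replicate 2. Gene lists counted as the same in 1081 settings. This meant the same side of the threshold or, with 1 section left out, a median within the standard deviation of the left-out medians. Another 208 were no longer called, 9 became called and 190 moved by more than that deviation. Changes of direction were counted only for lists called in the main setting, and numbered 16. The count of called genes for zone against distant tissue stayed between 8851 and 12327 under every setting. Other counts moved by more than 1.5 times. Against a fold change of 1.5, a stricter question by construction, the calls were 1956 for whole sections (main 5128), 1119 for border against distant tissue (3729) and 27 for region 1 (78). Thresholds of 1.45, 27.95 and 2.997 per 10000, which by construction shift spots between zone, border and distant tissue, gave 95, 10062 and 323 calls for border against distant tissue, and 27.95 gave 1805 for border against zone (9963). The DESeq2 test called 2425 for border against distant tissue, 26 in region 1, with 10731 genes set aside by its filter, and 21 in region 4 (0). Region 1 gave 42 calls with library size only, 163 with a total count of at least 10, 161 with the replicate block and 41 with distant tissue from 10 steps. It gave 0 with the region set by the cortical excitatory neuron list, which held 86.4% of region 1 and of which region 1 made up 35.8%. Region 4 gave 24 at resolution 1.0, in a region with 93.8% of its spots inside region 4. The striatal neuron and oligodendrocyte list regions hold few spots of either region and stand for neither. Leaving out 1 section, with fewer samples and the lone sample assumed to vary like the other group, gave 844 to 7105 calls for whole sections, 53 to 539 in region 1 and 2 to 53 in region 4. Gene lists called with an estimated correlation in place of the preset one numbered 0 higher and 0 lower in all 6 comparisons. Fry called 1 list lower for whole sections (5), 12 higher and 0 lower for border against distant tissue (21 and 4), 5 and 2 for border against zone (10 and 10) and 0 and 0 in region 1 (8 and 7) and region 4 (16 and 3). Ratios of list levels by distance at thresholds of 1.45, 27.95 and 2.997 per 10000 were 3.10, 6.46 and 3.87 for reactive astrocyte genes just outside the zone over far outside (8.30), 3.49, 8.84 and 3.53 for MHC class II (7.01), 3.66, 16.5 and 5.01 for interferon response (10.4) and 1.97, 11.5 and 2.47 for monocyte and macrophage genes (5.81). At 27.95 these means hide sections whose ratios moved opposite ways from their main values, with 2.84 and 10.1, 3.21 and 14.5, 5.06 and 27.9, and 4.74 and 18.3 in tumour replicates 1 and 2. Levels still fell off outward in both sections. The microglia ratio, edge over deep inside (2.51), was 1.60 and 2.10 at 1.45 and 2.997, and could not be had at 27.95, where a section had no spots 8 or more inside. Directions changed for border against distant tissue at 27.95 per 10000 in Aqp4 (-0.28), Cd79b (-0.44), Cx3cr1 (-0.34), Ppp1r1b (-0.14) and P2ry12 (-1.06, adjusted p = 0.00223), at 1.45 in Calb2 (1.70), Cd3g (-0.11) and P2ry12 (-0.12), at 2.997 in Calb2 (0.13) and P2ry12 (-0.20), and with a border of 5 steps in P2ry12 (-0.0559). For border against zone they changed at 27.95 in Cd3e (0.24), Ccl5 (0.0119), Gzma (0.0933), Gzmb (0.0924) and Klrk1 (0.20), at 1.45 in Cd4 (-0.13), Cx3cr1 (-0.23) and Gfap (-0.46), at 2.997 in Cx3cr1 (-0.0475) and with the zone set by clusters in Ms4a1 (-1.38), and for zone against distant tissue at 27.95 in Csf1r (-0.17) and Vegfa (0.26). Leaving out 1 section, values ranged for whole sections from -1.59 to 2.47 for Cd4; for border against distant tissue from -0.56 to 4.61 for Cd79b, -0.43 to 4.49 for Ms4a1, -0.12 to 4.27 for the B and plasma cell list and -1.12 to 0.37 for choroid plexus; and for border against zone from -0.77 to 2.28 for Ms4a1, each within 1 section and without a test for the zone comparisons. In region 1 they ranged from -0.00862 to 1.16 for Gfap, -0.47 to 0.43 for monocyte and macrophage, -0.0738 to 0.59 for extracellular matrix, -0.51 to 0.0128 for striatal neuron and -0.27 to 0.0875 for interneuron genes. In region 4 they ranged from -0.59 to 2.11 for extracellular matrix, -0.22 to 1.41 for endothelium, -0.40 to 1.93 for mural cell, -0.0612 to 0.95 for astrocyte, -0.44 to 0.0201 for synapse, -0.31 to 1.95 for meninges and -0.53 to 0.0682 for immediate early genes. Except where a setting's construction shows it, the cause was not tested. The sections share only a replicate number, and same-numbered sections' deviations from their group means correlated at -0.0454; with the replicate block 3733 genes were called for whole sections, 3617 of them shared, and Cd4 stood at 0.12. Sham totals were lower than those of the tumour sections, so genes with few sham counts have wide intervals, and in the simulated data the whole-section design recovered 14.1% of genes changed 2-fold and region 4 recovered 0%.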

Other observations

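Matrix and neuronal activity genes also differed between the zone and distant tissue, in edgeR's quasi-likelihood test unless camera is named. Extracellular matrix genes rose in 11 of 17 cases and fell in 2, with the collagen gene Col3a1 at 4.41 ± 0.30 and the fibronectin gene Fn1 at 2.64 ± 0.16 (camera adjusted p = 0.0107, 0.531 with an estimated correlation). Angiogenic endothelium genes were higher in 4 and lower in 3 of 9 cases and endothelium genes in 4 and 4 of 12, with neither list called. The adhesion gene Mcam rose by 4.28 ± 0.13 and Ly6c1, which has the close paralog Ly6c2, by 3.35 ± 0.15. Both are among the leading genes of the tumour-only region led by Hmga2, so they are not read as vessel genes here, while the receptor gene Flt1 and Itm2a were lower (-0.92 ± 0.13 and -1.22 ± 0.12). Mcam and Ly6c1 were lower in the border than in the zone (-3.17 ± 0.13 and -2.63 ± 0.15). The hypoxia list was not called (camera adjusted p = 0.719), with the stress gene Ndrg1 at -1.83 ± 0.17 and the growth factor gene Vegfa at -0.16 ± 0.13 (adjusted p = 0.292). Immediate early genes parted: the neuronal activity genes Arc and Egr1 fell (-4.08 ± 0.14 and -2.62 ± 0.14), and Jun and Ier2 rose (1.91 ± 0.12 and 2.09 ± 0.15), with 4 of 12 genes higher and 5 lower. In these lists the count adjusted over the list alone was the same.

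Reactive astrocyte genes were higher in the zone than in distant tissue in 8 of 12 cases and lower in 1 (camera adjusted p = 0.00451, 0.459 with an estimated correlation), although Gfap itself was not called there. The galectin gene Lgals1 rose by 4.15 ± 0.19. Ribosomal protein genes rose in 82 of 91 cases, with Rps20 at 2.85 ± 0.15 and near-identical pseudogene copies that can share reads (camera adjusted p = 2.68e-15, 0.531 with an estimated correlation). Border-associated macrophage genes rose in 6 of 9 cases without a call of the list (camera adjusted p = 0.164), and the mannose receptor gene Mrc1 stood at -0.89 ± 0.46 (adjusted p = 0.110; -0.13 without tumour replicate 1). In the border against distant tissue Aif1, a gene of microglia and macrophages, rose by 1.64 ± 0.12 and Aqp4, the astrocytic water channel gene, by 0.98 ± 0.13, while the astrocyte transporter gene Slc1a2 was lower (-0.52 ± 0.11).

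Of the tests below, all but the Cd4 test in striatal spots were chosen after the result was seen; for that one the ratio within a section was unseen, but the section totals and the border values were known. MHC class II genes were higher in region 1 of the tumour sections, 6 or more spots from the zone, than in sham tissue. Spread of RNA from the zone and its border could raise them. Their median excess over sham was 6.15% of their zone level. The 95th percentile was 3.48% for 52 genes outside the lists that the zone expresses and sham tissue lacks. By section the values were 7.12% against 4.05% and 4.74% against 2.95%, with 5 of the 8 genes above. This cannot decide on spread, since class II genes fell less from zone to border than zone genes such as Hmga2 and H19. Spread from the border, nearer to region 1, would raise their percent of the zone level more. The chemokine genes lay on both sides of that percentile (median 1.98%, with 4 of 11 above) and Gpnmb, at 1.06%, lay under the background median of 1.53%, so for them too spread stays open. For monocytes and macrophages in the mix of the zone, the excess of their own list was 1.56%, under the class II lower quartile of 3.13%. This cannot exclude them, since sham tissue of region 1 already held members such as S100a6 (49.7 CPM), which lowers the excess. Camera called the list higher in region 1, with Ifitm3 at 1.85 ± 0.30. Its median there was 0.09, and -0.47 without sham replicate 2. After thinning all libraries to the smallest total the class II median was 6.10. This cannot decide on deeper tumour libraries, since thinning draws evenly from a library and keeps the expected share of each gene. Sham tissue of region 1 held 1, 5 and 6 UMIs of H2-Aa, H2-Eb1 and H2-Ab1 before thinning. Depth in region 1 did not follow the groups, with 698371 and 3889915 UMIs in sham and 2223389 and 4883164 in tumour sections. Higher class II expression in cells of region 1 remains a hypothesis.

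Mitochondrial RNA was lower in tumour sections than in sham sections. A difference between the libraries of the groups as the whole cause is argued against within single libraries, where the zone lay under distant tissue by a median of -2.71 in the section with the smaller difference. Near-empty sham spots are argued against, since spots under 1000 UMIs held at most 2.46% of a sham section's UMIs, and the mitochondrial share differed by at least 6.38% of UMIs between a sham and a tumour section. In region 1, distant tissue differed from sham tissue by a median of -0.27. A lower mitochondrial share in the cells of the zone stays open, as does loss of RNA in damaged tissue, neither of which was tested.

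Cd4 was the T cell gene higher in the border than in the zone. Transcripts of striatal neurons were tested in the sham section with more striatal transcripts, where Cd4 was 39.8 times higher in the 25% of spots with the highest striatal level than in those under the median (51.4 against 1.29 CPM, 122 against 7 UMIs), with 0 UMIs of Cd3e and Cd8a in either. This is consistent with Cd4 reads from striatal tissue, and the other sham section had 9 against 1 UMIs. More T cells at the border are argued against by the T cell list median of -0.73, border minus zone, where 14 of the 17 members other than Cd4 were below 0 and 0 were above Cd4. Microglia or macrophages as a source of Cd4 were not tested.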
